A study of Mus musculus with 48 samples.

How the data were processed

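Kidney RNA was measured on Affymetrix mouse arrays in a factorial experiment with 3 factors, each at 2 levels: genotype (mice carrying the Hyp mutation or normal mice), diet (low phosphate or control) and sex. Hyp is a mutation of the X-linked gene Phex, so Hyp males carry no normal copy. Hyp females were taken to carry 1 normal and 1 mutant copy, which was not checked here. Per the labels, the diets were given for 3 days and the mice were 10 weeks old. RNA from 72 mice was combined into 24 pools of 3 mice, giving 8 groups of 3 pools. Each pool was hybridised to 2 chips, the 430A and the 430B, for 48 arrays in all. Total RNA was prepared with TRIzol and labelled with biotin by the Affymetrix protocol, per the labels' protocols. Because the replicates are pools of different mice, the spread between pools is smaller than the spread between single animals would be, and the p-values refer to pools.

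The deposited values are signal intensity per probe set on a linear scale, 1 table per array. The arrays were processed with GCOS 1.2, per the submitters' processing notes; the expression algorithm, the scaling target and the mask are not given in the sources used here. The tables hold 22690 probe sets on the 430A chip and 22575 on the 430B chip, with 64 control probe sets on each. On every array the mean of the 100 probe sets that both chips carry, with 2% trimmed at each end, came to 1200, so the deposited intensity was already scaled on these probe sets. No detection calls were used, so a probe set near background is known only by its low signal. The median signal of an array lay between 164.6 and 211.1 on the 430A chip and between 50.8 and 68.3 on the 430B chip. Arrays give no read depth, and their number limits the precision. Pairs of pools of the same group correlated at r = 0.923 to 0.946 across features, which are not independent replicates.

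Gene symbols came from the probe annotation table given with the platform, updated through Entrez identifiers against the gene table of assembly GRCm38.p6, which was used only for names, chromosomes and gene order. Of the 45137 probe sets that are not controls, 35041 had 1 gene symbol, 936 had several and 9160 had none; 34837 were matched by identifier. A probe set was kept if its signal exceeded the array's median on at least 3 of the 24 arrays of its chip. Each gene was represented by the kept probe set with the highest mean log2 signal, taken from the 430A chip where it had one. Kept probe sets with no or several symbols were tested and not named. This left 18642 features, of which 12838 had a gene name. Among genes past the threshold with several kept probe sets, no pair was called in opposite directions for genotype or diet. For sex this happened for 8 genes: Ercc2, Farsa, H2aj, Mettl7a1, Nectin3, Rsrp1, Ube2d3 and Vma21. A further probe set passed in the same direction for 51 of 137 genes with several kept probe sets for genotype. These counts were 22 of 52 for diet, 536 of 1155 for sex, 1 of 1 for genotype by diet and 0 of 3 for genotype by sex.

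Signals were floored at 1, taken to log2 and fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The model had 8 group means, and each comparison was a contrast of these means with equal weights. The chips were fitted separately, and p-values were adjusted by the Benjamini-Hochberg method over the features of both chips together, with a threshold of 0.05. The 3 main effects set 12 pools against 12. The 4 interactions, and the effects within 1 genotype, diet or sex, came from the same fit. Values after ± are standard errors of log2 differences unless an SD is named. All adjusted p-values are limma's unless another test is named, and a gene is said to have risen or fallen only where its adjusted p passed the threshold.

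A total of 41 gene lists (pathways, nephron segments and other cell types or tissues) was tested with limma's camera at a preset correlation of 0.01, for the 3 main effects and the genotype by diet interaction. Lists needed at least 4 measured members, which 37 had. The lists of mineralization regulators (3 measured), Y-linked genes (2), muscle (2) and pancreas (2) were too small. Beside each call stands the adjusted p of camera with an estimated correlation. Genes were named by a rule: for each main effect, the 10 largest rises and the 10 largest falls by fold among genes past the threshold with the same sign in all 4 strata of the other factors; for each interaction, the 10 smallest p-values past the threshold; from each list, up to 4 members with the smallest adjusted p; and 20 mineral, sex and kidney genes whatever their values. Of these 20, Phex, Ddx3y, Ren1 and Trpv5 had no named feature here. Gene models without a proper name were left out where the rule allowed it. Genes shared by lists of calls, and the liver genes and clock genes in the closing part, are named outside this rule and were chosen after their values were seen. The design, the gene lists, the rule and the alternatives were fixed before the data were examined.

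The alternatives were quantile normalization, scaling of each array to a common median, a pseudocount at the 20th percentile of signal (42.6 on the 430A chip and 14.9 on the 430B chip), no filter, a stricter filter at the 75th percentile, every probe set as a feature, a variance trend with intensity, array weights, the replicate number as a block, adjustment within each chip, and leaving out each pool or each replicate number. A fold of a gene near background understates or overstates the change depending on the pseudocount, so group signals are given for such genes.

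Before use, the fit was tested on simulated data: 18642 features were drawn around their real means and spreads, with 50 features changed at each of 4 sizes. For the genotype contrast 26% of features changed 1.25-fold, 52% of those changed 1.5-fold, 70% of those changed 2-fold and 92% of those changed 4-fold were recovered. For the diet contrast the shares were 20%, 68%, 78% and 96%. For sex they were 24%, 58%, 86% and 94%. For the genotype by diet interaction 46% of features changed 2-fold and 60% of those changed 4-fold were recovered. For the genotype by sex interaction these shares were 66% and 78%, for the diet by sex interaction 64% and 76%, and for the three-way interaction 6% and 46%. In a separate simulation 4 of 4 shifted gene lists were recovered, and no unshifted list was called. The noise was drawn independently for each feature, so false list calls from correlated genes could not arise in it.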

Results

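The data are 24 kidney RNA pools in 8 groups of 3, formed by genotype (normal or Hyp), diet (control or low phosphate) and sex. The sex labels were checked first. Xist, the RNA that silences 1 X chromosome in females, had a mean signal of 1723 ± 194 (SD, n = 12) in female pools and 124.5 ± 33.7 in male pools. The Y-linked gene Eif2s3y had 260.5 ± 31.9 in male pools and 3.13 ± 1.79 in female pools. The mutated gene Phex checked nothing. The 2 probe sets for it never exceeded a signal of 32.8 and 49.8, below the lowest array median of 164.6. Both were removed by the filter. In a separate limma fit of every probe set without the filter, they gave log2 differences between Hyp and normal pools of -0.18 ± 0.68 and -0.22 ± 0.34 (adjusted p = 0.981 and 0.943).

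The first comparison asked how Hyp kidneys differ from normal kidneys over both diets and both sexes. Ttr, which encodes the plasma carrier transthyretin, was 8.38-fold higher in Hyp pools (log2 3.07 ± 0.09, 12 pools against 12), a size that is uncertain because some Hyp signals lay near the top of the array range. The other Ttr probe sets had lower highest signals of 13966, 22230 and 22400. Their mean signals were 9727, 15970 and 11870 in Hyp pools and 1191, 2198 and 1182 in normal pools. Cyp24a1, the enzyme that breaks down active vitamin D, rose 3.67-fold (1.88 ± 0.14). Dnase1, a secreted deoxyribonuclease, was 4.23-fold lower (-2.08 ± 0.10). The sodium-phosphate cotransporter genes Slc34a3 and Slc34a1 fell by 0.61 ± 0.08 and 0.30 ± 0.06 on the log2 scale, and Kl, the coreceptor of the phosphate hormone FGF23, fell by 0.69 ± 0.07. In all, 194 features were higher and 169 lower by limma, and 1994 had an unadjusted p under 0.05 where chance would give 932.

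Other large rises were Gulo, which completes vitamin C synthesis (2.43 ± 0.21), the carboxylesterase gene Ces1g (2.52 ± 0.21), Fabp1 (1.81 ± 0.32), Cyp4b1 (1.53 ± 0.10, near the top of the range in males), Tmem252 (1.39 ± 0.11), the leukotriene C4 synthase gene Ltc4s (1.30 ± 0.10) and Apoc1 (1.27 ± 0.16). Gulo signals were low, 52.5 ± 23.4 (SD, n = 12) in normal and 271.3 ± 101 in Hyp pools, and the pseudocount reduced its difference to 1.70. That of Fabp1, at 81.3 ± 54.6 and 258 ± 177, was then 1.21. Ces1g had signals of 140.1 ± 157 (SD, n = 12) in normal and 1080 ± 1035 in Hyp pools. It exceeded the array median on only 10 of 24 arrays, so its size is uncertain. The SDs of Ces1g span both sexes, which differed by 3.05 ± 0.21 (male minus female). Gulo and Fabp1 exceeded the array median on 9 and 7 arrays, all of them Hyp, and so passed the filter only through Hyp pools. Fndc9 (1.59 ± 0.40) lost its call without any 1 of 20 pools. Large falls were seen for Ugt2b37 (-1.70 ± 0.36), Car3 (-1.45 ± 0.12), the integrin gene Itgb6 (-0.92 ± 0.09), the zinc transporter gene Slc30a2 (-0.88 ± 0.09), Nepn (-0.84 ± 0.12), Susd2 (-0.81 ± 0.06), Cpeb3 (-0.78 ± 0.14), Frs3 (-0.76 ± 0.17) and Bhmt (-0.76 ± 0.15). For Ugt2b37, which has a low signal in females, the pseudocount gave -0.96.

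Among phosphate transporters and their scaffolds, 3 of 10 measured members fell and none rose: Slc34a3, Slc34a1 and the scaffold gene Pdzk1 (-0.31 ± 0.06). Adjusted over the list alone 5 fell and 1 rose, and the list was lower by camera (adjusted p = 8.8e-04, and 0.00814 with an estimated correlation). Slc34a2 (0.32 ± 0.14), Slc20a1 (-0.01 ± 0.08), Slc20a2 (-0.16 ± 0.11) and Nherf1 (-0.04 ± 0.09) did not pass. In the vitamin D list of 10, Cyp24a1 rose and Cyp27b1, which makes active vitamin D, fell by 1.72 ± 0.26 with the parathyroid hormone receptor gene Pth1r (-0.42 ± 0.04). The same 3 were called over the list alone, and the list as a whole did not pass (adjusted p = 0.182). Vdr gave 0.16 ± 0.07 (adjusted p = 0.376). The value for Cyp27b1 averages opposite signs: 1.59 ± 0.37 on the control diet (not past the threshold) and -5.04 ± 0.37 on the low phosphate diet. Its signals were low, and the pseudocount gave -0.78.

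Of the calcium-binding proteins of the distal tubule, S100g (-1.10 ± 0.09), Calb1 (-0.33 ± 0.08) and Pvalb (-0.31 ± 0.07) fell, the last losing its call without the filter. S100g gave 0.20 ± 0.13 on the control diet and -2.40 ± 0.13 on the low phosphate diet, and Calb1 gave -0.01 ± 0.11 and -0.66 ± 0.11, neither passing on the control diet. These were the 3 calls of the calcium and magnesium list of 12, also over the list alone, and the list did not pass (adjusted p = 0.155). Slc12a3, the thiazide-sensitive cotransporter of the distal convoluted tubule, rose by 0.50 ± 0.05. In the list of Klotho, FGF receptors and FGF response genes, Dusp6 (0.84 ± 0.09), Etv5 (0.60 ± 0.12) and Spry2 (0.49 ± 0.10), which FGF signalling induces, rose and Kl fell. Over the list alone 6 rose and 1 fell of 15. Its call (adjusted p = 0.0272) was lost with an estimated correlation (adjusted p = 0.0585), and Fgfr1 gave -0.13 ± 0.10.

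The nephron segment lists moved in different directions. Of 7 intercalated cell genes, Slc4a1 (0.42 ± 0.09), Slc26a4 (0.27 ± 0.05) and Atp6v0d2 (0.32 ± 0.08) rose, and all 7 rose when adjusted over the list alone (camera adjusted p = 4.78e-09, and 0.00134 with an estimated correlation). Atp6v0d2 stood at the threshold and lost its call without any 1 of 23 pools. In the convoluted proximal tubule list of 9, the glucose cotransporter gene Slc5a2 (-0.64 ± 0.06), Slc34a1, Slc4a4 (-0.28 ± 0.05) and Slc22a6 (-0.23 ± 0.05) fell and Slc22a8 (0.31 ± 0.06) rose. Over the list alone 6 fell and 1 rose, and the list was lower (adjusted p = 3.33e-06, and 0.00711 with an estimated correlation). In the straight proximal tubule list of 8, Cyp7b1 (0.67 ± 0.11), Slc22a19 (0.39 ± 0.06) and Slc5a1 (0.35 ± 0.06) rose. Over the list alone 5 rose and 1 fell, and the list was higher (adjusted p = 1.79e-04, and 0.00691 with an estimated correlation). These 3 lists and the phosphate transporter list were the only calls of 8 that held with an estimated correlation.

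The other calls were smaller. Kidney injury markers were higher (Clu 0.30 ± 0.06 and Fga 0.47 ± 0.11 of 10; 4 over the list alone; adjusted p = 0.0232, and 0.0551 with an estimated correlation). Ammoniagenesis and acid-base genes were lower (Slc4a4, Car12 -0.23 ± 0.05 and Car4 -0.38 ± 0.08 of 11; over the list alone 4 fell and 2 rose; adjusted p = 0.0232, and 0.0874 with an estimated correlation). For oxidative phosphorylation none of 36 members passed limma's test, over all features or over the list alone. The list's call at a median of -0.04 (adjusted p = 0.0272) had an adjusted p = 0.498 with an estimated correlation. Other calls, from lists that did not pass or, for Alpl, were too small to test, were Alpl (-0.44 ± 0.06), Slc22a12 (-0.39 ± 0.07), Slc7a12 (0.79 ± 0.12), Slc7a8 (-0.43 ± 0.09), Ier3 (0.78 ± 0.09), Xbp1 (0.32 ± 0.06), Pfkp (0.34 ± 0.05), Acaa2 (0.26 ± 0.05) and Cyp2e1 (-0.30 ± 0.06). The value for Slc7a12 averages unlike effects in males and females, given below. Beside Pfkp, Ldha of the glycolysis list fell (-0.19 ± 0.05), and beside Ier3, Ier2 of the immediate early list rose (0.33 ± 0.08), calls lost without any 1 of 16 and 11 pools. The other 29 lists had medians between -0.15 and 0.15 and adjusted p-values from 0.063 to 0.99. Among them, no leukocyte, endothelium, podocyte, adrenal or red blood cell member passed limma's test over all features. In the fat list, which did not pass as a list, Car3 of 4 measured members fell.

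**Figure D1:**
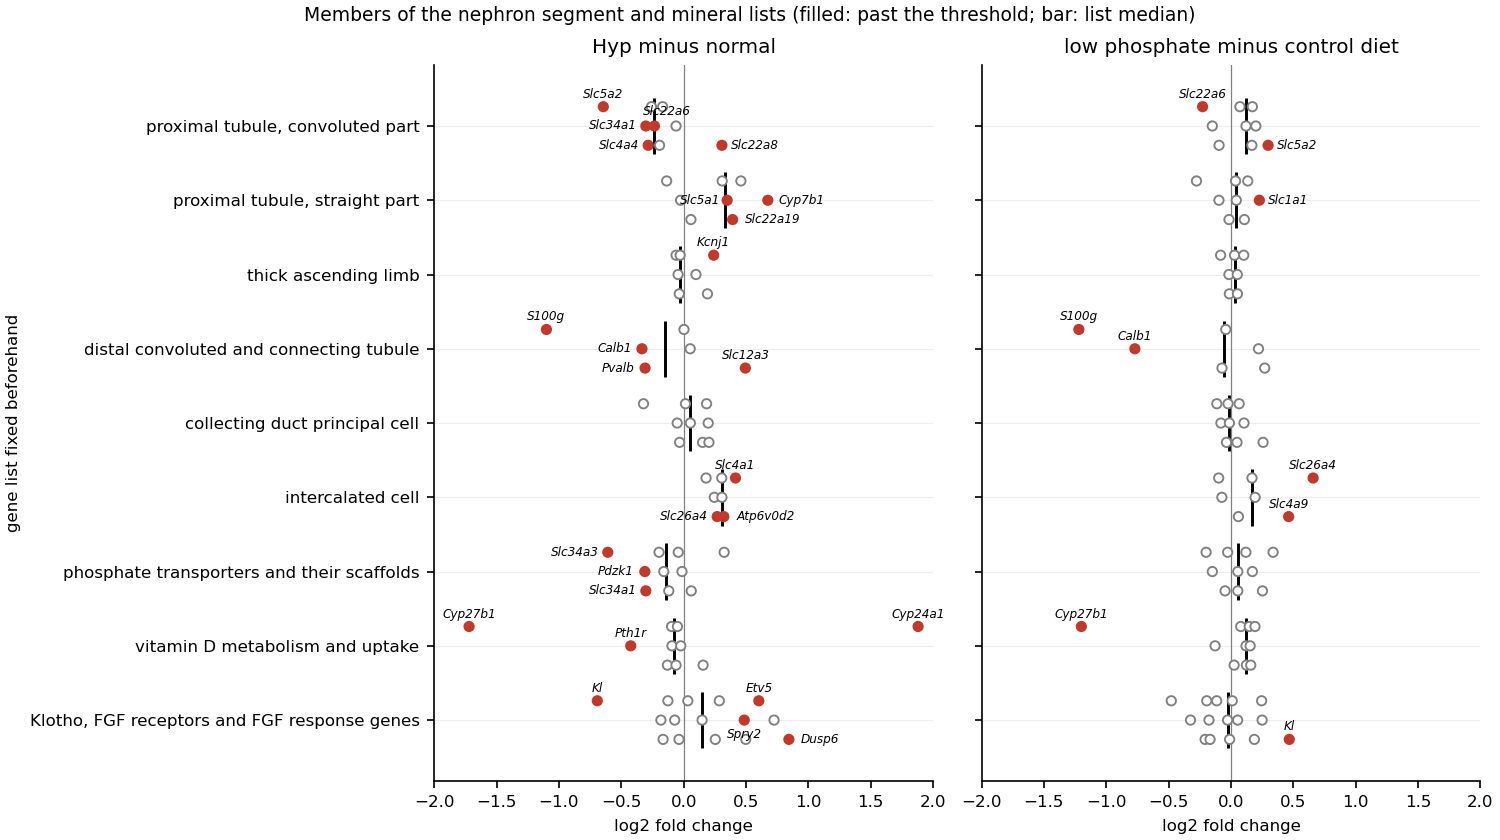
Log2 fold changes (x axis) of the measured members of 9 gene lists for Hyp minus normal (left) and low phosphate minus control diet (right), with genes past the limma threshold filled and named and the list median as a bar. All 7 intercalated cell genes lie above 0 for genotype, while Slc5a2, Slc34a1 and Slc34a3 lie below it.

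Within each diet the genotype effect was called for 77 higher and 47 lower features on the control diet and for 89 higher and 56 lower on the low phosphate diet. Both lists shared 44 higher and 18 lower features, where independent lists would share 0.37 and 0.14. Of the 124 called on the control diet, 123 had the same sign on the low phosphate diet. Dnase1 was 4.49-fold and 3.99-fold lower, and Kl differed by -0.65 ± 0.11 and -0.74 ± 0.11, Slc34a3 by -0.56 ± 0.11 and -0.66 ± 0.11, and Gulo by 2.34 ± 0.30 and 2.53 ± 0.30. Slc34a1 differed by -0.30 ± 0.09 and -0.31 ± 0.09, which did not pass within either diet (adjusted p = 0.17 and 0.13).

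The second comparison asked what 3 days of low phosphate diet changed over both genotypes and both sexes. Mdk, the growth factor midkine, rose 2.44-fold (1.29 ± 0.07, 12 pools against 12) and Itgb6 2.15-fold (log2 95% interval 0.90 to 1.30). The chloride-iodide exchanger gene Slc26a4 rose by 0.66 ± 0.05, the membrane carbonic anhydrase gene Car4 by 0.69 ± 0.08 and Kl by 0.47 ± 0.07. Tmem252 fell by 1.48 ± 0.11, Ttr by 1.23 ± 0.09 and Calb1 by 0.77 ± 0.08. S100g fell by 1.22 ± 0.09 on average, with 0.08 ± 0.13 in normal and -2.52 ± 0.13 in Hyp pools. The gluconeogenic gene Pck1 fell by 0.74 ± 0.09. In all, 78 features rose and 66 fell by limma, with 1772 at an unadjusted p under 0.05 against 932 by chance. Scaling arrays to a common median gave 58 higher of 134. Without the filter 94 passed.

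Further rises were Gcgr, the glucagon receptor gene (0.73 ± 0.14), Angptl4 (0.78 ± 0.16, lost without the filter), Derl3 (0.64 ± 0.11) and Cdk1 (0.64 ± 0.12). Slc22a27 (1.41 ± 0.24) lost its call with the pseudocount, which gave 0.41, and Gm6958 (1.27 ± 0.28) without any 1 of 15 pools. Further falls were Aldh1a7 (-0.92 ± 0.08), Alb (-0.78 ± 0.15), Cyp4b1 (-0.76 ± 0.10), Tcf24 (-0.75 ± 0.09), Ces1g (-0.97 ± 0.21, lost without any 1 of 6 pools) and Dzip1 (-1.08 ± 0.22, lost with adjustment within each chip). No phosphate transporter passed by limma. Slc34a1 gave 0.17 ± 0.06 (adjusted p = 0.314), Slc34a3 0.34 ± 0.08 (adjusted p = 0.061), Slc34a2 -0.20 ± 0.14, Slc20a1 0.25 ± 0.08, Slc20a2 0.05 ± 0.11 and Pdzk1 0.12 ± 0.06. Over the list alone 3 of the 10 members rose, and the list did not pass (adjusted p = 0.0942). Cyp24a1 gave -0.13 ± 0.14 and Vdr 0.19 ± 0.07.

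For diet 11 lists were called by camera, and none kept its call with an estimated correlation (adjusted p-values from 0.105 to 0.25). Among ammoniagenesis and acid-base genes (lower, adjusted p = 0.0114, and 0.105 with an estimated correlation), Pck1, the glutamine transporter gene Slc38a3 (-0.66 ± 0.08) and Glud1 (-0.47 ± 0.06) fell. Car4 and Rhcg (0.24 ± 0.05) rose, and over the list alone 5 fell and 3 rose of 11. Intercalated cell genes were higher (adjusted p = 0.00254, and 0.105 with an estimated correlation). Slc26a4 and Slc4a9 (0.46 ± 0.08) rose of 7, also over the list alone. In the distal convoluted and connecting tubule list (lower, adjusted p = 0.0114, and 0.135 with an estimated correlation), S100g and Calb1 fell. Over the list alone 1 member of 6 also rose.

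Cholesterol synthesis genes were lower (Nsdhl -0.31 ± 0.06, Ebp -0.27 ± 0.05 and Msmo1 -0.47 ± 0.10 of 17; 6 over the list alone; adjusted p = 0.0187, and 0.105 with an estimated correlation). NRF2 and glutathione genes were lower (Gsta2 -0.62 ± 0.07 of 15; 5 over the list alone; adjusted p = 0.0114, and 0.105 with an estimated correlation). Amino acid transporters were higher (Slc7a7 0.34 ± 0.06, Slc1a1 and Slc3a2 of 17; 4 over the list alone; adjusted p = 0.0114, and 0.105 with an estimated correlation). Cell cycle genes were higher (Cdk1 of 14; 4 over the list alone; adjusted p = 0.00831, and 0.105 with an estimated correlation). Glycolysis genes were higher (Ldha 0.29 ± 0.05 of 10, also over the list alone; adjusted p = 0.0187, and 0.105 with an estimated correlation). Fatty acid oxidation genes were higher (adjusted p = 0.0168, and 0.25 with an estimated correlation): Acot1 rose by 0.53 ± 0.09 and Ppara fell by 0.46 ± 0.11 of 20, also over the list alone. The call of Ppara was lost without any 1 of 20 pools, and those of Slc1a1 and Slc3a2 without any 1 of 17 and 19. For fatty acid synthesis no member of 9 passed limma's test over all features and 2 fell over the list alone (lower, adjusted p = 0.0359, and 0.121 with an estimated correlation).

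The vitamin D list was called higher (adjusted p = 0.0338, and 0.135 with an estimated correlation), with a median of 0.12 and a mean of -0.03. Its 1 member past the threshold over all features, Cyp27b1, fell on average (-1.20 ± 0.26), while over the list alone 5 rose and 1 fell of 10. This average hides opposite responses, a rise of 2.11 ± 0.37 in normal and a fall of 4.51 ± 0.37 in Hyp pools. The average fall was lost with the pseudocount, which gave -0.34, without the filter, and without any 1 of 10 pools. The other 26 lists had medians between -0.09 and 0.17. Other calls were Slc22a12 (0.37 ± 0.07), Slc5a2 (0.30 ± 0.06), Cela1 (0.38 ± 0.05), Odc1 (-0.34 ± 0.06) and Ctsa (0.28 ± 0.06, lost with median scaling).

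The next comparison asked whether Hyp mice respond to the diet as normal mice do. Cyp27b1, S100g and Ttr were the features whose diet response differed between the genotypes by limma's interaction test. In normal pools the diet raised Cyp27b1 by 2.11 ± 0.37, from 70.5 ± 25.5 (SD, n = 3) to 368.2 ± 76.9 in males and from 83.3 ± 21.4 to 304.4 ± 130 in females. In Hyp pools it lowered Cyp27b1 by 4.51 ± 0.37, from 171.6 ± 44.4 to 8.10 ± 2.98 in males and from 346.9 ± 253 to 15.2 ± 9.35 in females. The interaction was -6.62 ± 0.53 (adjusted p = 5.59e-07). The low phosphate Hyp signals lay far below the array median, and those of normal pools on the control diet were low too. The size is therefore uncertain, and the pseudocount gave -3.95. On the control diet Cyp27b1 was higher in Hyp by 1.59 ± 0.37 without passing (adjusted p = 0.0542), and on the low phosphate diet it was lower by 5.04 (-5.04 ± 0.37).

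S100g gave 0.08 ± 0.13 on the diet in normal pools (adjusted p = 0.91) and fell by 2.52 ± 0.13 in Hyp pools. In Hyp males its signal was 9176 ± 1725 (SD, n = 3) on the control and 1589 ± 195 on the low phosphate diet, and in Hyp females 12777 ± 2857 and 2218 ± 330. The interaction was -2.60 ± 0.19 (adjusted p = 1.74e-07). Ttr fell on the diet by 1.84 ± 0.12 in normal and by 0.62 ± 0.12 in Hyp pools (interaction 1.22 ± 0.17, adjusted p = 0.00392). In Hyp males on the control diet its signal of 26986 ± 3365 (SD, n = 3) lay near the highest of the arrays (30303 to 47504), so the size of this interaction is uncertain too. Another Ttr probe set also passed for the interaction in the same direction. The highest signals of the other Ttr probe sets were 13966, 22230 and 22400. Cyp24a1 gave -0.79 ± 0.19 in normal and 0.53 ± 0.19 in Hyp pools, and neither these nor the interaction of 1.32 ± 0.27 passed (adjusted p = 0.21). Calb1 gave -0.45 ± 0.11 and -1.09 ± 0.11, with an interaction of -0.65 ± 0.15 that did not pass (adjusted p = 0.353).

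**Figure D2:**
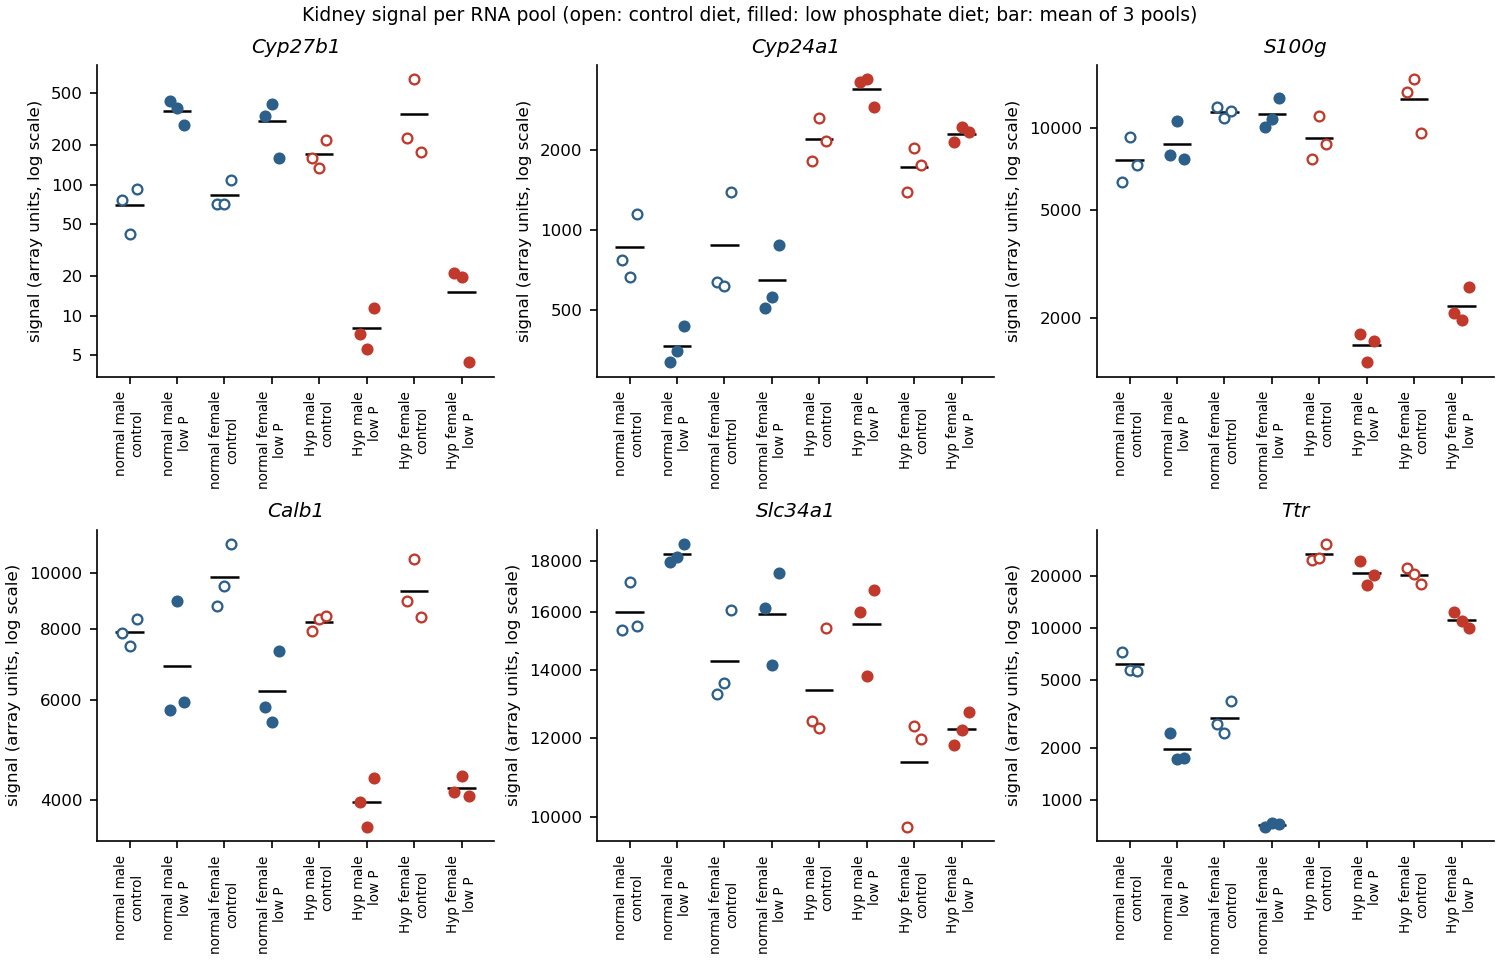
Signal (array units, log scale) of 6 genes in each RNA pool by group, with normal pools in blue and Hyp pools in red, the control diet open and the low phosphate diet filled, and the mean of 3 pools as a bar. On the low phosphate diet Cyp27b1 rises in normal pools and falls to means of 8.10 and 15.2 in Hyp pools, where S100g and Calb1 are also lowest.

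The remaining response pointed the same way in both genotypes for most called features. By limma 37 features rose and 50 fell on the diet in normal pools, and 12 rose and 16 fell in Hyp pools. Of the 87 called in normal pools 81 had the same sign in Hyp pools, and of the 28 called in Hyp pools 24 had the same sign in normal pools, which share no arrays with them. The calls shared 5 rises (Mdk, Itgb6, Slc26a4, Car4 and Cela1) and 9 falls (among them Tmem252, Ttr, Aldh1a7, Tcf24, Pck1 and Slc38a3), where independent lists would share 0.02 and 0.04. Mdk rose by 1.52 ± 0.10 and 1.05 ± 0.10, Slc26a4 by 0.67 ± 0.08 and 0.65 ± 0.08, and Car4 by 0.71 ± 0.12 and 0.67 ± 0.12 in normal and Hyp pools. Pck1 fell by 0.86 ± 0.12 and 0.62 ± 0.12. Kl gave 0.51 ± 0.11 and 0.42 ± 0.11, the second not past the threshold (adjusted p = 0.22). Slc34a1 gave 0.17 ± 0.09 in each genotype, neither past the threshold. Over all 18642 features the responses correlated at r = 0.03, with a jackknife error of 0.06.

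These counts depended on single pools. In normal pools 47 features passed without the filter, 52 without normal female control diet replicate 1, and 57 without normal male control diet replicate 1 or without normal female control diet replicate 2. In Hyp pools 18 passed without low phosphate male replicate 1, low phosphate male replicate 2 or low phosphate female replicate 3, and scaling to a common median gave 6 higher of 23, while a variance trend gave 45 calls. For the interaction 1 feature was higher and 2 were lower, with 1003 at an unadjusted p under 0.05 against 932 by chance. Without normal female control diet replicate 3 there were 5 calls, and with a variance trend 9. No gene list passed by camera for the interaction (smallest adjusted p = 0.0952, for the distal convoluted and connecting tubule). That list had an adjusted p = 0.597 with an estimated correlation and 0.031 with fry, which asks only whether the genes of a list move 1 way.

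The genotype and diet effects were then set against each other. Of 363 features called for genotype, 107 (29.5%) had the same sign for diet, and of 144 called for diet, 50 (34.7%) had the same sign for genotype. Of the features called in both, 38 had opposite and 14 equal signs. Thus 23 features were lower in Hyp and higher on the diet, among them Kl, Itgb6, Car4, Alpl, Slc5a2, Slc22a12, Slc2a2, Bmp6 and Car14. Another 15 were higher in Hyp and lower on the diet, among them Ttr, Tmem252, Cyp4b1, Aldh1a7, Ces1g and the sulfate transporter gene Slc13a1. In both comparisons 9 were lower, with Cyp27b1, S100g, Calb1, Slc22a6, Bhmt and Fmo1, and 5 were higher (Apoe, Apom, Dpp7, Mdk and Slc26a4). Independent lists would share 0.71, 0.69, 0.60 and 0.81 features. Cyp27b1 and S100g are lower in both through the Hyp pools on the low phosphate diet. For diet in normal pools they gave 2.11 ± 0.37 and 0.08 ± 0.13, and for genotype on the control diet 1.59 ± 0.37 and 0.20 ± 0.13. The contrasts subtract no common control group, but both are drawn from the same pools. Their errors are therefore uncorrelated only where all groups have equal spread. The contrasts also share 1 estimate of the spread per feature, which adds to shared calls in every direction. Over all features r was -0.08 with a jackknife error of 0.24 (covariance -0.00385). It ranged from -0.143 to -0.0175 with 1 pool left out and from -0.1716 to -0.0268 over the alternatives that keep all pools. The spread was not equal. Root mean square deviations (log2) were 0.466, 0.459 and 0.445 in Hyp female control diet pools and 0.372 to 0.431 in all other pools. That group is added in the genotype contrast and subtracted in the diet contrast, so its noise makes the covariance more negative. Its share of the covariance of -0.00385 was not tested.

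Set instead against the same control pools, the genotype effect on the control diet and the diet effect in normal mice correlated at r = 0.425 (covariance 0.0394), and 63.6% of features had the same sign. Simulated groups without any effect gave r = 0.502, a covariance of 0.0422 and 66.9%, because both comparisons subtract the same 6 pools. With these pools split between the comparisons r was 0.00 (from -0.07 to 0.03 over 18 splits). The covariance lay 0.0028 below the simulated one (-0.0028).

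**Figure D3:**
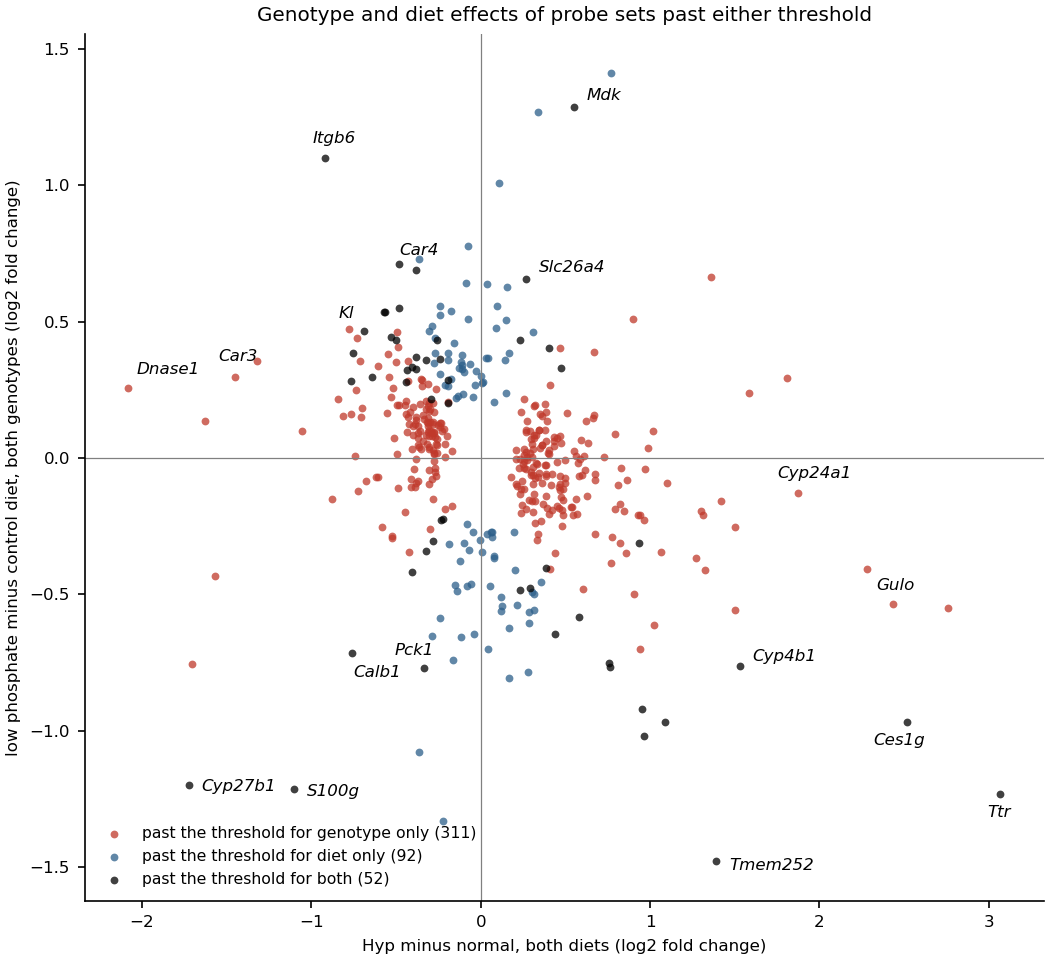
Log2 fold change of Hyp minus normal (x axis) and of low phosphate minus control diet (y axis) for each feature past the limma threshold in either, coloured by which threshold it passed. Of the features past both, 38 lie in the quadrants of opposite sign and 14 in those of equal sign, and Cyp27b1 and S100g at the lower left are averages over genotypes whose diet responses differ (Cyp27b1 2.11 on the diet in normal and -4.51 in Hyp pools).

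Sex had the largest number of calls. Acsm3, an acyl-CoA synthetase gene, had a mean signal of 6406 ± 751 (SD, n = 12) in males and 42.1 ± 29.5 in females (log2 7.59 ± 0.26, and 6.32 with the pseudocount), and the bile acid gene Cyp7b1 5878 ± 2127 and 122 ± 31.9 (5.54 ± 0.11). Higher in males were also Cyp2j13 (6.64 ± 0.27), Slc7a13 (5.82 ± 0.17), Ugt2b37 (5.74 ± 0.36), Slco1a1 (5.70 ± 0.30), Pzp (5.26 ± 0.44), Cyp4a12a (4.06 ± 0.19) and Serpina1b (3.71 ± 0.44). The lower sex had signals near background for most of these, so the sizes depend on the floor. In females the means were 52.7 ± 27.9 (SD, n = 12) for Cyp2j13, 41.9 ± 29.4 for Ugt2b37, 31.9 ± 23.2 for Slco1a1, 50.8 ± 51.7 for Pzp, 76.0 ± 32.9 for Cyp4a12a and 46.9 ± 36.2 for Serpina1b. With the pseudocount Cyp2j13 gave 5.61, Slc7a13 5.55, Ugt2b37 4.28, Pzp 3.86, Cyp4a12a 3.35 and Serpina1b 2.45. Higher in females were Abcc3 (-4.32 ± 0.21, male minus female), the amino acid transporter gene Slc7a12 (-4.02 ± 0.12), Akr1c18 (-3.15 ± 0.11), Slc22a29 (-2.94 ± 0.08), Pcolce2 (-2.80 ± 0.36) and Cox8b (-2.69 ± 0.30), of which Abcc3, Pcolce2 and Cox8b had means of 60.8 ± 23.8, 33.0 ± 23.2 and 39.8 ± 27.7 in males and gave -3.53, -1.59 and -1.65 with the pseudocount. Slc17a2 (-5.04 ± 0.13), Hdc (-3.99 ± 0.36), Slc22a27 (-3.67 ± 0.24) and Eif2s3y (6.61 ± 0.15) were near background in 1 sex, and the pseudocount gave -2.44, -1.65, -1.76 and 2.72. By limma 1131 features were higher and 1823 lower in males, with 5119 at an unadjusted p under 0.05 against 932 by chance. Scaling arrays to a common median gave 1397 higher of 2725, so the balance of directions depends on the scaling.

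Of 12 genes listed beforehand as sex-biased in kidney, 9 were higher in males and 2 in females, also over the list alone (camera adjusted p = 1.99e-10, and 1.34e-04 with an estimated correlation). They include Cyp2e1 (3.22 ± 0.06), Cyp4b1 (2.99 ± 0.10) and Cyp4a14 (-2.42 ± 0.10). The size for Cyp4b1 is uncertain, since its male mean of 27164 ± 4094 (SD, n = 12) lay near the highest signals of the arrays. Kap, the androgen-regulated kidney protein gene, gave -0.07 ± 0.08 (adjusted p = 0.59), with mean signals of 36912 ± 4239 and 38894 ± 4591 (SD, n = 12) in males and females. Those highest signals were 30303 to 47504, so Kap lay at the top of the range and its test says nothing about a sex difference. In the straight proximal tubule list 5 members were higher and 2 lower in males of 8, also over the list alone (adjusted p = 8.6e-04, and 0.0131 with an estimated correlation). Xist (-3.84 ± 0.13), Eif2s3x (-0.65 ± 0.07) and Kdm6a (-0.91 ± 0.14), of 5 genes on X inactivation and escape, were lower in males, and 4 were over the list alone (adjusted p = 2.09e-04, and 0.00972 with an estimated correlation).

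All 8 interferon response genes were lower in males, also over the list alone (adjusted p = 1.39e-04, and 0.0161 with an estimated correlation), with Rtp4 (-0.70 ± 0.09), Bst2 (-0.61 ± 0.11), Ifit3 (-0.49 ± 0.09) and Irf7 (-0.48 ± 0.10) leading. Principal cell genes were lower in males (5 of 9 and 7 over the list alone; adjusted p = 0.00238, and 0.0161 with an estimated correlation), with the water channel gene Aqp4 at -1.28 ± 0.09 and the sodium channel gene Scnn1g at -0.39 ± 0.09. Another 8 lists were called and lost their call with an estimated correlation (adjusted p-values from 0.0813 to 0.155). Lower in males were extracellular matrix (8 of 15, with Lum -1.19 ± 0.11 and Fn1 -0.69 ± 0.09; 10 over the list alone; adjusted p = 0.0813 with an estimated correlation) and leukocyte genes (6 of 13, with Cd52 -0.49 ± 0.09; 7 over the list alone; adjusted p = 0.15 with an estimated correlation). Immediate early genes were lower too (7 of 13, with Ier3 -0.75 ± 0.09; 9 over the list alone; adjusted p = 0.115 with an estimated correlation), as were endothelial genes (4 of 9, with Emcn -0.41 ± 0.06; 4 over the list alone; adjusted p = 0.0945 with an estimated correlation).

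Intercalated cell genes (4 of 7, with Atp6v1b1 -0.32 ± 0.07; 6 over the list alone; adjusted p = 0.0968 with an estimated correlation) and distal convoluted tubule genes (4 of 6; 4 over the list alone; adjusted p = 0.155 with an estimated correlation) were lower in males. So were calcium and magnesium genes (6 of 12, with S100g -0.48 ± 0.09 and Casr -0.41 ± 0.08; 7 over the list alone; adjusted p = 0.0968 with an estimated correlation). Among organic anion and cation transporters 8 were higher and 4 lower of 16, also over the list alone, with Slc22a6 at 1.23 ± 0.05, Slc22a2 at 0.81 ± 0.06 and Slc22a19 at -0.95 ± 0.06 (adjusted p = 0.115 with an estimated correlation). The median of all features was -0.05 for males minus females, on the side of the lists lower in males.

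Other sex differences lay in lists that did not pass or, for Mgp, were too small to test. Elovl6 (-1.32 ± 0.07) and Scd1 (-0.91 ± 0.06) of fatty acid synthesis, Gsta4 (-2.03 ± 0.08) and Abcc4 (-1.07 ± 0.11) of the NRF2 list, the mineralization inhibitor gene Mgp (-0.80 ± 0.07) and Sgk1 (-1.07 ± 0.14) were lower in males. Idi1 (2.00 ± 0.06), Me1 (1.14 ± 0.05), Havcr1 (0.79 ± 0.13) and Car4 (0.76 ± 0.08) were higher. Slc34a1 (0.24 ± 0.06) and Kl (0.35 ± 0.07) were higher in males, while Cyp27b1 (-0.35 ± 0.26), Cyp24a1 (0.04 ± 0.14) and Calb1 (-0.11 ± 0.08) did not differ past the threshold. Of the fat markers, Adipoq (-0.63 ± 0.16), Retn (-0.52 ± 0.09) and Fabp4 (-0.37 ± 0.10) were lower in males and Car3 (0.48 ± 0.12) higher.

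The last comparisons asked whether the mutation or the diet acts differently in males and females. In males 148 features were higher and 51 lower in Hyp by limma, and in females 53 were higher and 76 lower. Scaling to a common median gave 62 higher of 119 in females, and the count of 129 there was 83 without the filter and 196 with the stricter filter. The calls shared 33 rises and 18 falls, where independent lists would share 0.42 and 0.21, and 175 of the 199 called in males had the same sign in females. Ttr was higher by 2.77 ± 0.12 and 3.37 ± 0.12, Cyp24a1 by 2.29 ± 0.19 and 1.46 ± 0.19, and Kl lower (-0.61 ± 0.11 and -0.78 ± 0.11) in males and females.

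The genotype effect differed between the sexes for 15 features, of which 10 have a gene name. Cyp4b1 had a signal of 29355 ± 5098 (SD, n = 3) in normal and 30036 ± 1446 in Hyp males on the control diet, and 2510 ± 515 and 11035 ± 802 in females. Its genotype effect was 0.18 ± 0.14 in males and 2.87 ± 0.14 in females (interaction -2.69 ± 0.20, adjusted p = 1.89e-07). The male signals lay near the highest of the arrays (30303 to 47504), where a rise could go unregistered, so the size of the interaction is uncertain. Azgp1, also higher in normal males than females, behaved alike (0.22 ± 0.14 and 1.43 ± 0.14, adjusted p = 0.00781). Rdh16f2 (1.74 ± 0.08 in males and 0.12 ± 0.08 in females, adjusted p = 1.58e-07) and Slc7a12 (1.62 ± 0.17 and -0.03 ± 0.17, adjusted p = 0.0016), both higher in females, rose in Hyp males. Pigr, the polymeric immunoglobulin receptor gene, is higher in males and rose in Hyp males (1.09 ± 0.17, and -0.60 ± 0.17 in females). Slco1a6 fell in Hyp males (-0.52 ± 0.09) and gave 0.37 ± 0.09 in females. Slc22a8, Slc9a8 and Aldh1a7 had interactions of 0.71 ± 0.12, 0.75 ± 0.14 and 0.83 ± 0.16. Median scaling ended each of these 3 calls, and leaving out any 1 of 15 and 19 pools ended the last 2. Without Hyp female control diet replicate 1 there were 24 calls, with the stricter filter 27 and with a variance trend 28.

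**Figure D4:**
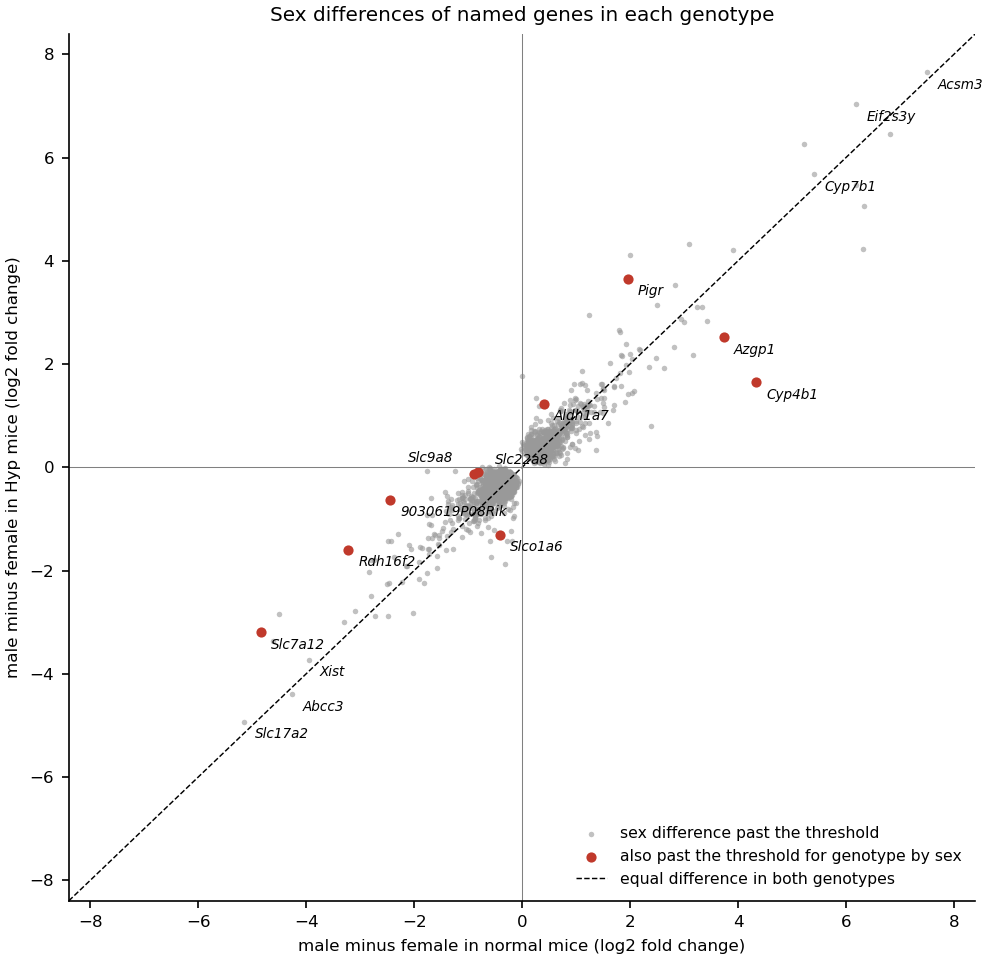
Male minus female log2 fold change in normal mice (x axis) and in Hyp mice (y axis) for the named genes with a sex difference past the limma threshold, with the 10 genes past the genotype by sex threshold in red and the line of equal differences dashed. Most genes lie near the line, and Cyp4b1 and Azgp1 lie below it while Rdh16f2, Slc7a12 and Pigr lie above it.

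Neither the diet by sex interaction nor the three-way interaction gave a call by limma. For diet by sex 1019 features had an unadjusted p under 0.05 against 932 by chance, and the smallest adjusted p was 0.0977. For the three-way interaction there were 724, and the smallest adjusted p was 0.347. A diet by sex call appeared in some alternatives, 1 with the pseudocount, 1 without the filter, 2 with the stricter filter and 3 with a variance trend.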

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

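The gene and sex patterns tested in this part were picked from the results above, so their tests were chosen with those results in view. Of the predictions, only that for the count of liver genes that stay near background was written after the outcome was seen. The results below were picked out because limma's test of the difference between 2 groups passed. Between the genotypes the diet response differed for Cyp27b1 (-6.62), S100g (-2.60) and Ttr (1.22). Between the sexes the genotype effect differed for Rdh16f2 (1.62), Cyp4b1 (-2.69), 9030619P08Rik (1.82), Slco1a6 (-0.89), Pigr (1.70), Slc7a12 (1.65), Azgp1 (-1.21), Slc22a8 (0.71), Slc9a8 (0.75) and Aldh1a7 (0.83). These are log2 differences of differences. Only named genes are listed.

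The diet response of Cyp27b1 and S100g in Hyp pools was set against the noise of low signals and against a single pool. If noise near background made the difference for Cyp27b1, it should disappear with a pseudocount at the 20th percentile of signal, and it stayed at -3.95 (adjusted p = 2.5e-07). For S100g, whose group means were 1589 or higher, the pseudocount moves nothing and tests nothing. If a single pool made it, leaving that pool out should end the call. Over the fits that leave out 1 pool the largest adjusted p was 3.03e-06, so a single pool does not account for either gene, nor noise near background for Cyp27b1. The difference lies between pools labelled Hyp and normal, labels that the Phex probe sets could not check. Other differences between these groups of mice were not tested.

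Ttr, Gulo and Ces1g, which are abundant in liver, were higher in Hyp pools, so liver tissue among the Hyp samples was weighed against the genotype. In the planned test the median difference of 9 measured liver transcripts was 0.47 with a bootstrap error of 0.175, and 3 of the 9 rose. This met neither planned bound and did not decide. The 9 genes were those kept by the filter, which Fabp1 passed only through Hyp arrays, so the set depends in part on the outcome. The bootstrap error treats the genes as independent. In the test chosen afterwards, liver at the share that the Ttr signal would need should bring all abundant liver transcripts, yet 14 of 24 listed genes with a named probe set never exceeded the array median. The highest signal among these was 197.6, against a Ttr mean of 19816 ± 6343 (SD, n = 12) in Hyp pools. Signals of different probe sets are not on a common scale. The values therefore argue against liver tissue at that share without excluding it, and do not decide on a smaller share. A single pool is excluded for Ttr, since its lowest difference with 1 pool left out was 3.03. Gulo and Ces1g were not part of that test.

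The differences between the sexes were smaller in Hyp than in normal pools on balance. The slope of the genotype by sex interaction on the sex difference was -0.065 over the 2954 features with a sex difference, and 1759 of them differed less in Hyp. Over all features this interaction had a median of 0.0472, and of 0.0023 with quantile normalization and 0.0121 with median scaling. Because 1823 of the 2954 were lower in males, such a common shift adds to the count of 1759. If a narrower signal range of the Hyp arrays were the cause of the smaller differences, Xist and the Y-linked genes would shrink as well, and the median of 5 was -0.21. Of these, Orly and Tspy-ps differed by only 0.17 and 0.13 between the sexes in normal pools and so cannot shrink; the others gave -0.21 (Xist), 0.85 (Eif2s3y) and -0.59 (Uty), which go both ways and decide nothing. Among 100 assignments of the genotype labels, the real one included, 3 gave a slope as far below 0, the lowest other being -0.0866, and a narrower range may still account for the slope.

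The labels were also reassigned within the strata of the other 2 factors, 100 assignments for each comparison with the real one included, which asks only whether chance can be excluded. For genotype 1 of 100 gave as many calls as the real 363 (highest other 13), for diet 1 (144; highest other 5) and for sex 1 (2954; highest other 212). The assignment behind the 212 calls exchanged the labels of only 2 male and 2 female pools, so part of the sex difference remained in it. For the genotype by diet interaction 3 gave as many as the real 3 calls (highest other 3), and for the genotype by sex interaction 2 gave as many as 15 (highest other 163). That assignment exchanged the genotype of all 12 male pools and of 2 female pools, which turns a genotype effect common to both sexes into an interaction, and the next highest gave 4. For the diet by sex interaction and the three-way interaction limma gave 0 calls (1019 and 724 features at an unadjusted p under 0.05; highest other 2 and 8). There 100 of 100 give as many by construction, so the count says nothing about chance.

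For the effects within 1 group, 1 of 100 assignments, the real one, gave as many calls in each case. The counts were 87 for diet in normal pools (highest other 8), 28 for diet in Hyp pools (highest other 12), 124 for genotype on the control diet (highest other 26) and 145 on the low phosphate diet (highest other 7). For genotype in males the count was 199 (highest other 154, from the assignment that exchanged all 12 male pools, a structure and not chance) and in females 129 (highest other 4).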

How the results depend on the processing

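All alternatives here were planned before the data were examined, and the causes of changes were not tested unless stated. Of 281 named calls, median scaling ended 29, no filter 37 of 279, quantile normalization 19 and every probe set 10. The stricter filter kept only 230 of the 281 for testing and ended 0 of these, and the others were not tested under it. Each of the other settings that keep all pools ended at most 6. Leaving out 1 pool ended 12 to 26. Leaving out replicate number 1, 2 or 3 in all groups ended 126, 129 and 103, and no setting reversed a call. With single pools or a whole replicate number left out (fewer samples), counts ranged from 102 to 369 for genotype (363 with all), 23 to 140 for diet (144) and 1524 to 3031 for sex (2954). They were 2 to 5 for genotype by diet (3), 4 to 24 for genotype by sex (15), 0 to 1 for diet by sex (0) and 0 to 1 for the three-way interaction (0). For diet they were 7 to 95 in normal mice (87) and 8 to 24 in Hyp mice (28). For genotype they were 21 to 127 on the control diet (124), 31 to 164 on the low phosphate diet (145), 40 to 221 in males (199) and 22 to 133 in females (129). Gene lists were not run with single pools left out, and without a whole replicate number 20 to 25 passed (32 with all). The correlation of the diet responses (0.03) ranged from -0.0034 to 0.0543, turning to -0.0002 without Hyp male control diet replicate 2 and to -0.0034 without Hyp female control diet replicate 2. Without the filter (more features tested) diet had 94 calls, diet in normal mice 47, genotype in females 83 and diet by sex 1. With the stricter filter (fewer features) genotype by sex had 27, diet by sex 2, genotype in females 196, and the correlation was 0.1425. With a variance trend genotype by diet had 9, genotype by sex 28, diet by sex 3 and diet in Hyp mice 45, and with the pseudocount diet by sex had 1. Gene list calls were 9 with an estimated correlation and 53 with fry. With the replicate number as a block the counts were 438 for genotype, 185 for diet, 3250 for sex, 3 for genotype by diet and 20 for genotype by sex; within-group residuals of the same number correlated at -0.052 to 0.0871, below the planned bound of 0.1 for using the block, yet 22 of 24 pools were closest to their own number (mean r 0.03, and -0.015 to other numbers), and replicate 3 was positive in all 8 groups on the first component of within-group variation (12.1%), so a small effect shared by replicate number is present. Low signal over background limits Phex, Cyp27b1 in Hyp pools on the low phosphate diet and in normal pools on the control diet, Ces1g in normal pools, Gulo and Fabp1.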

Other observations

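The genes of this part were chosen after their values were seen. Of 363 features called for genotype, 109 were higher in Hyp and lower in males, where independent lists would share 19, and 75 were lower in Hyp and higher in males, where 10.3 would. Another 30 were higher in both and 24 lower in both, against 11.8 and 16.5. Slc7a12 (0.79 ± 0.12 for genotype, -4.02 ± 0.12 for sex), Ier3 (0.78 ± 0.09 and -0.75 ± 0.09) and Slc22a19 (0.39 ± 0.06 and -0.95 ± 0.06) belong to the first kind. Kl (-0.69 ± 0.07 and 0.35 ± 0.07) and Car3 (-1.45 ± 0.12 and 0.48 ± 0.12) belong to the second. The genotype value of Slc7a12 averages unlike effects in males and females (interaction 1.65). The genotype and sex contrasts share 1 estimate of the spread per feature and are drawn from the same pools. The group with the largest spread, Hyp females on the control diet, enters these contrasts with opposite signs. What this adds to the counts of opposite sign was not tested. The X chromosome held 10 genotype calls among 387 tested genes against 300 among 12451 on other chromosomes (Fisher p = 0.737), and of 50 tested neighbours of Phex only S100g was called.

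The 13 measured clock genes are given by the replicate number of the pools, as values without a test. The numbers balance genotype, diet and sex. Dbp had mean signals of 1191 ± 446, 951 ± 414 and 425 ± 366 in replicates 1, 2 and 3 (SD, n = 8 each), and Nr1d2, which encodes a clock repressor, 1992 ± 263, 1805 ± 406 and 1046 ± 424. Arntl, which drives both, had 185 ± 39.6, 216 ± 63.9 and 309 ± 86.7, and Tef 2112 ± 315, 1909 ± 196 and 1514 ± 388. Per2 had 204 ± 54.8, 165 ± 51.6 and 114 ± 82.9, Per3 245 ± 37.1, 178 ± 47.2 and 157 ± 59.4, and Ciart 103 ± 33.7, 95 ± 57.6 and 46.7 ± 37.1. Clock had 254 ± 43.0, 250 ± 41.8 and 264 ± 54.2, Per1 190 ± 52.7, 185 ± 59.6 and 173 ± 52.4, Nr1d1 293 ± 84.7, 292 ± 84.5 and 250 ± 89.3, and Bhlhe40 914 ± 197, 939 ± 257 and 820 ± 302. Hlf had 1048 ± 218, 918 ± 104 and 815 ± 136 and Usp2 1509 ± 237, 1387 ± 181 and 1225 ± 243.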
